A study of Homo sapiens with 6 samples.

How the data were processed

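RNA sequencing was carried out on 6 samples of U2OS cells transfected with a control shRNA or with either of a pair of shRNAs against CACTIN. The deposited table has no header line: each of its 3171202 lines holds a feature name, a position and numbers in 6 unnamed columns. It has 193511 transcript lines, 1585601 exon lines and 1392090 intron lines, and 0 lines name a sample. The unit of the numbers is not given in the sources used here. CASAVA 1.8.2 and the build hg19 are named in the submitters' processing notes. The aligner, the counting method and any use of strand are not given in the sources used here.

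None of the 6 columns could be matched to a sample by a name, and matching by column order or by the values themselves, such as a low CACTIN value, would be a guess. No result was computed from these columns. Their cells were checked to be numbers, and the values of the first listed transcript in the first of the columns were compared by hand with those of its exons. The transcript value times its exonic length equalled the sum over its exons. This would hold for RPKM and for other values divided by length, so it does not settle the unit of the deposited values. The gene-level, intron-level, exon-level and gene list tests planned before the data were examined, with all of their alternatives, were not run, and no comparison between groups was made.

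Feature names and positions were read with Python 3.11.15. Transcript lines carried RefSeq names in 35577 cases, UCSC names in 73777 and Vega names in 96927, and a line can carry several. Exons and introns with the same chromosome, start and end were counted once. Strand was taken from the order of exons. An intron was counted as overlapping when at least 1 of its bases lay within the union of all listed exons, whatever their strand, and the overlap count was tested on made-up intervals with known answers. RefSeq accessions were given symbols from a RefSeq gene table of GRCh38, used for names alone, which matched 32883 of 34256 accessions, 96.0%. Positions are those of the table, with both ends counted as inside the feature. CACTIN, DHX8, SRRM2 and the introns of CDCA5 were named under a rule fixed before the data were examined, while the IER2 and ARF6 exceptions were named after they were seen.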

Results

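RNA was sequenced from U2OS, a human osteosarcoma cell line, 48 h after transfection with shRNA plasmids. The design holds 3 groups of 2 samples each: a control shRNA (shCtrl) and the shRNAs shCac_C and shCac_D, both directed against CACTIN, a protein studied here for its part in pre-mRNA splicing and sister chromatid cohesion. Reads were single-end and 100 bases long. The deposited table gives numbers for each listed transcript, exon and intron in 6 columns, which carry no names. None of the 6 columns could be matched to a sample, so no expression level, intron level or difference between shCtrl, shCac_C and shCac_D is reported, CACTIN knockdown included. The depth of each sample is unknown. What follows describes the genes and introns that the table covers, from their names and positions alone.

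CACTIN, the gene targeted by both shRNAs, lies on the minus strand of chromosome 19 in hg19, as judged from the order of its exons. Its longer listed RefSeq messenger RNA, NM_001080543, spans positions 3610627 to 3626813 and has 10 exons, 9 introns and 3624 exonic bases. A second CACTIN transcript, NM_021231, spans positions 3610643 to 3626813 and is divided into 11 exons. The introns of NM_001080543 range from 90 to 4285 bases, and 2 of the 9 overlap an exon of another listed transcript. For NM_021231, 3 of 10 introns do. DHX8, an RNA helicase that acts late in splicing, lies on the plus strand of chromosome 17 from 41561334 to 41601680. It has 23 exons, 22 introns of 93 to 5263 bases, and 4200 exonic bases, and 0 of its introns overlap an exon of another listed transcript. SRRM2, a large nuclear protein rich in serine and arginine that associates with the spliceosome, lies on the plus strand of chromosome 16 from 2802330 to 2821413. It has 15 exons, 14 introns of 92 to 3487 bases, and 9353 exonic bases, and 1 intron overlaps another exon.

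CDCA5 encodes sororin, which stabilises cohesin on replicated chromatids. In the table it lies on the minus strand of chromosome 11 from 64844927 to 64851615, with 6 exons, 5 introns and 2576 exonic bases. Intron 1 covers positions 64851196 to 64851404 and intron 2 covers 64851023 to 64851100. Intron 3 covers 64850872 to 64850956, intron 4 covers 64847260 to 64850835, and intron 5 covers 64846660 to 64846824. Introns 2 and 3, of 78 and 85 bases, are shorter than a read, as are the shortest introns of CACTIN, DHX8 and SRRM2. Intron 2 overlaps no listed exon, whereas the other 4 introns each overlap an exon of another transcript. As for CACTIN, DHX8 and SRRM2, the exons of all listed transcripts on either strand were used. By the same rule, 30.3% of the distinct introns of RefSeq transcripts across the table overlapped an exon. No count against RefSeq exons alone was made for these genes.

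Across the table, 193511 transcript lines were divided into 466932 distinct exons and 309459 distinct introns. The median length of a distinct intron was 1832 bases, and 13926 introns, 4.50% of the total, were shorter than a read. At least 1 base of 124444 distinct introns, 40.2%, lay inside an exon of some listed transcript on either strand. With introns and exons of RefSeq transcripts alone, the count was 16688 of 201077 introns, 8.30%. Transcript lines with a single exon made up 4.32% of all transcript lines, 8362 lines in all.

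The gene lists chosen for this design held 499 entries, of which 475 were found by RefSeq symbol. All 25 cohesion genes, among them SMC1A, SMC3, RAD21 and NIPBL of the cohesin ring and its loader, were found, and so were all 25 mitotic genes, 25 replication genes and 24 p53 targets. In the spliceosome core 44 of 44 genes were found by symbol, and 24 of 25 among the second-step and late factors. A gene not matched by symbol, such as DHX16 in that last list, is not shown to be absent. Of 24 genes listed as intronless, 22 were found and 20 of these had no intron in any RefSeq transcript. The others were IER2 and ARF6. Of 13 replication-dependent histone genes, 11 had no intron. None of the 13 mitochondrially encoded genes, which are counted among the 499 entries, was found. Symbols were looked up only through RefSeq names of the NM and NR kinds. The lack of a match therefore does not show that these genes are absent.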

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

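The intron overlap and its alternatives were chosen after seeing the data. The share of distinct introns overlapping a listed exon, 40.2% with all transcripts, was 8.30% when introns and exons were restricted to RefSeq transcripts and 35.5% when at least 50 bases had to overlap. It was 40.2% without unplaced and random sequences. Restricting the exons alone to RefSeq gave 18.9%, and restricting the introns alone gave 30.3%. Removing exons or asking for more overlapping bases could not raise the share, so the direction of those changes was fixed beforehand. Restricting the introns alone could have moved the share either way, and it lowered it. No paired analysis was possible because the columns carry no sample names or replicate numbers. The other settings fixed before the data were examined were not run, since they need values matched to samples.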
